A study of Fragaria x ananassa with 18 samples.

How the data were processed

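Leaf transcriptomes of the cultivated strawberry (Fragaria x ananassa, cultivar Elsanta) were measured by poly(A)-selected RNA sequencing on an Illumina HiSeq instrument, per the labels' protocols. Plants grew in a greenhouse at 20 °C in white peat, in peat with 3% biochar or in peat with 3% chitin, and 84 plants were grown per treatment. Leaflets were inoculated at 8 weeks with agar discs carrying mycelium of Botrytis cinerea, the grey mould fungus, or received plain agar discs as the mock treatment. Libraries were labelled as leaves of plants aged 9 weeks. The 3 substrates and the 2 disc treatments gave 6 groups with 3 libraries each, 18 in all. The labels number the libraries of a group but do not say that they came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

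The values used were whole-number counts of reads per gene model, deposited by the authors in a table of 45377 gene models and not normalized. FastQC 0.11.8, Trimmomatic 0.38, STAR 2.6.1d and edgeR 3.4.3 are named, per the submitters' processing notes. The read counter, its strand setting, its treatment of reads with several alignments and the reference genome are not given in the sources used here. The cultivated strawberry is octoploid, so a gene model can share reads with near-identical copies on the other subgenomes, and every value given for a single gene model is uncertain to that extent. Reads of a gene and an overlapping or antisense partner could not be told apart either. All columns of the table matched a library, and it held 0 rows of unassigned or total counts.

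None of the gene model identifiers (0 of 45377) matched the gene table of the strawberry reference used here, which has 77630 rows and belongs to another cultivar. Gene models are therefore given by identifier alone, without product names or positions. The 38 gene lists fixed before the data were examined and the shares of plastid, mitochondrial and fungal transcripts were not analysed here, since no identifier could be assigned to a list. No identifier began with a prefix of the fungus (0 of 45377), so fungal load was not measured.

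Counts were analysed with R 4.3.3 and edgeR 4.0.16. Gene models were kept by filterByExpr with the 6 groups (minimum count 10, minimum total count 15), which left 14946 of the 34162 gene models with at least 1 count and 99.7% to 99.8% of the counts of each library. Library sizes were scaled by TMM. A single model of the 6 groups was fitted to all 18 libraries with robust quasi-likelihood dispersions, and 13 contrasts were tested two-sided with the quasi-likelihood F test and Benjamini-Hochberg adjustment within each contrast. A gene model was called at an adjusted p under 0.05. By chance, 747 of the 14946 gene models would fall under an unadjusted p of 0.05. The common biological coefficient of variation was 35.5%. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. CPM were computed with the cpm function of edgeR on TMM-scaled library sizes, and means are given with the SD over 3 libraries. Log2 CPM for principal components, correlations and scores used a prior count of 2.

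The contrasts were chitin, biochar and inoculation effects within each level of the other factor, chitin against biochar in mock leaves, the interactions of each amendment with inoculation, and effects averaged over the other factor. Averaged effects weigh the substrates or the disc treatments equally. The rule for naming gene models was fixed before the data were examined. It takes, per contrast, at most 2 identifiers per direction with the largest log2 fold change among those called, with a mean of at least 5 CPM in the higher group and, in contrasts of 2 groups, no overlap between their libraries. The most abundant gene model over all libraries together was added after its values were seen. For 3 libraries against 3, an exact permutation test gives p = 0.1 at the smallest, so such tests cannot pass 0.05. Where a group held 0 counts of a gene model, the fold is a bound against 3 counts over that group; with few counts (1, 3 and 5 in the lower group or groups of 3 named gene models), a ratio of pooled counts is given with its 95% interval from the exact binomial distribution. Shares of a library total carry 95% exact binomial limits. Intervals and bounds cover counting error only.

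The fitting was tested on counts simulated for the 14946 tested gene models with 200 gene models changed. For chitin against peat in mock leaves, edgeR recovered 59% of the gene models changed 4-fold and 11% of those changed 2-fold, and 5.41% of its 74 calls were false. For biochar against peat in mock leaves it recovered 49% and 9%, with 1.69% of calls false. For inoculation in biochar it recovered 65% and 6%, with 5.33% of calls false. For inoculation averaged over substrates it recovered 86% and 46%, with 8.97% of calls false. DESeq2 made more false calls on the same simulations, from 10.5% of calls for chitin averaged over disc treatments to 20.5% for inoculation averaged over substrates. Its larger counts below may therefore carry more false calls. The self-test was first set to stop the analysis for any of the 3 tools whose false calls passed 15% of calls. DESeq2 passed that limit, the stop was then kept for edgeR and limma voom alone, and DESeq2 was kept as an alternative. The simulations did not cover the fit without a filter on low counts, nor libraries that stand apart from their group, so these rates may not hold for the real counts.

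Total counts ran from 6834147 to 11839584 per library. Replicate libraries differed by far more than sampling noise (chi-square per degree of freedom 16.0 to 163), and no pair of them held identical values. Alternatives set before the data were examined were no filter on low counts, at least 5 CPM in 3 libraries, median-of-ratios size factors, DESeq2 1.42.0, limma voom (limma 3.58.1), the replicate number as a block, fits of only the 2 groups compared, a threshold of 1 on the absolute log2 fold change, and leaving out each library in turn. Leaving out 2 libraries that stood apart, limma voom with sample quality weights, thinning to one total, and the scores per library were added after the data were seen. Figures were drawn with matplotlib 3.10.9.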

Results

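The series comprised 18 leaf libraries of strawberry plants aged 9 weeks, 3 for each combination of substrate (peat, peat with 3% biochar, peat with 3% chitin) and disc treatment (mock or B. cinerea). Biochar is charred plant material, here holm oak pyrolysed at 650 °C, and chitin is the N-acetylglucosamine polymer of fungal walls and crustacean shells, here flakes from crab shells. Total counts per library ranged from 8014182 to 8621551 in mock peat, 8433108 to 8558119 in mock biochar and 6834147 to 11839584 in mock chitin. In inoculated leaves they ranged from 7669272 to 9164560 in peat, 7596862 to 9933544 in biochar and 7603054 to 11205786 in chitin. Within groups, Pearson correlations of log2 CPM across gene models ran from 0.903 in inoculated chitin to 0.974 in inoculated peat.

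The leading principal components of the 1000 most variable gene models held 32.4% and 23.7% of their variance. All 3 mock chitin libraries and inoculated chitin replicates 1 and 2 lay at 8.35 or higher on component 2, as did mock peat replicate 3 at 11.5. Inoculated chitin replicate 3 lay at -29.5, beside biochar and inoculated peat libraries. Mock peat replicate 1 lay at -23.3 on component 1, where the other mock peat libraries lay at 24.2 and 26.6 and the inoculated peat libraries between -15.1 and -12.7. Its correlation with inoculated peat libraries (0.9502 to 0.958) exceeded that with the other mock peat libraries (0.912 and 0.930). Group labels were used as given, and counts without these libraries are given beside the results they move.

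**Figure D1:**
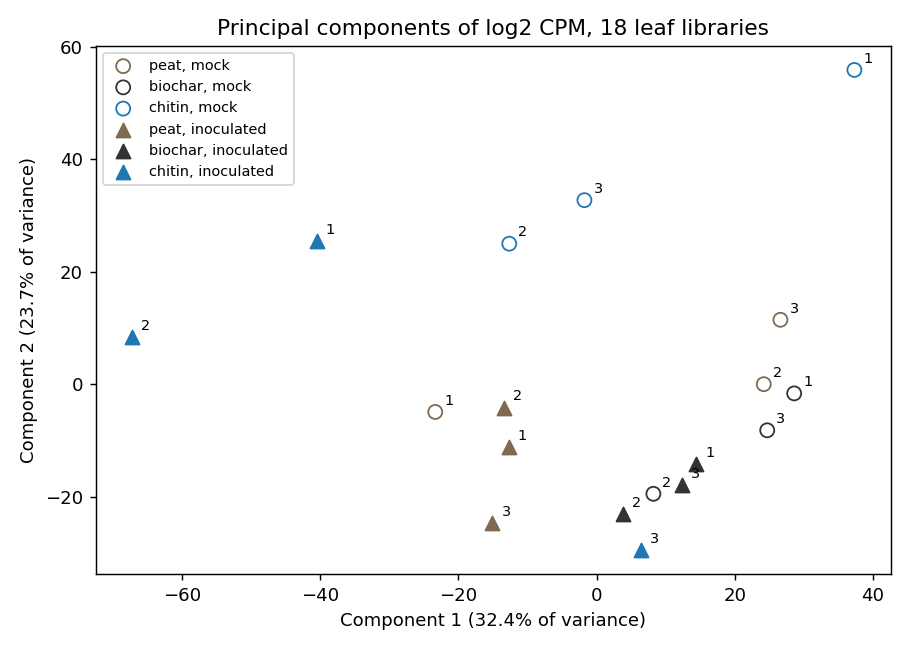
Principal components of log2 CPM over the 1000 most variable gene models in 18 libraries, with the share of variance on each axis. Open circles are mock and filled triangles inoculated leaves, coloured by substrate, and digits are replicate numbers. Inoculated chitin replicate 3 lies at -29.5 on component 2, while the other chitin libraries and mock peat replicate 3 lie at 8.35 or higher.

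The most abundant gene model over all libraries together, FANhyb_rscf00002550.1.g00001.1, rose with inoculation. In most mock libraries FANhyb_rscf00001570.1.g00001.1 was more abundant, for example at 3.48% in mock biochar replicate 1. Chosen after its values were seen, FANhyb_rscf00002550.1.g00001.1 took 1.26% ± 0.36 (SD, n = 3) of the counts in mock peat leaves and 6.38% ± 0.41 in inoculated peat leaves. In chitin it went from 1.30% ± 0.95 to 7.46% ± 3.05, and in biochar from 1.43% ± 0.66 to 3.31% ± 0.76. All 9 inoculated libraries lay above every mock library, from 2.53% (95% interval 2.51% to 2.54%) upward against at most 2.20% (2.19% to 2.21%). An exact permutation test within substrates gave a two-sided p of 0.00025, the smallest it can give. The choice by total counts, inoculated libraries included, favours a gene model high after inoculation, and this p is not adjusted for it. In edgeR's quasi-likelihood test the averaged log2 fold change was 2.01 ± 0.28 (SE), with an adjusted p of 0.000474. Within substrates the edgeR log2 fold changes were 2.28 in peat (adjusted p = 0.0529), 1.21 in biochar (adjusted p = 0.979) and 2.55 in chitin (adjusted p = 0.0146). The interactions with biochar (log2 -1.07 ± 0.67, adjusted p = 1.00) and chitin (0.27 ± 0.67, adjusted p = 0.979) were not called by edgeR. In peat it was called in 8 of 16 other settings, among them DESeq2 (adjusted p = 0.000228), the edgeR replicate block (adjusted p = 0.0498) and an edgeR fit of only the 6 peat libraries (adjusted p = 0.0327). The call in chitin was lost without inoculated chitin replicate 2 (edgeR adjusted p = 0.0689) and in an edgeR fit of only the 6 chitin libraries (adjusted p = 0.210).

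**Figure D2:**
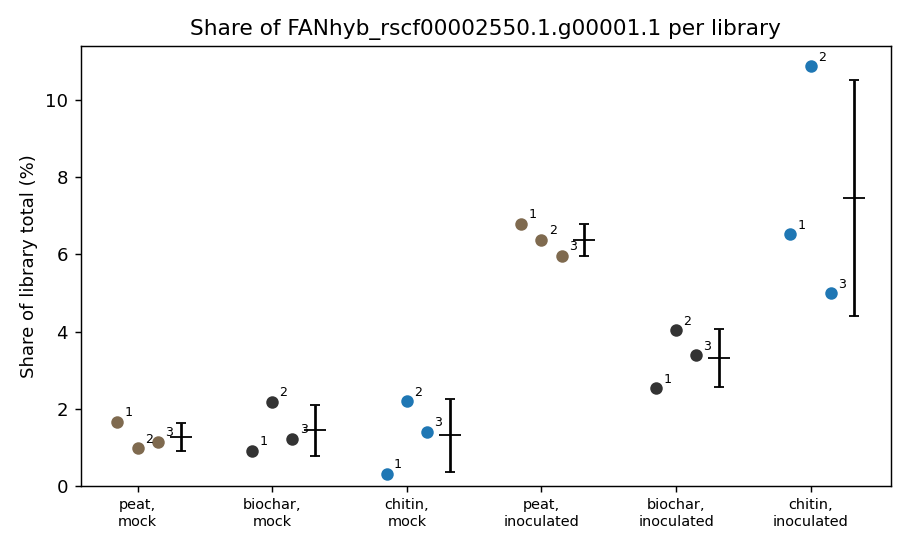
Share of FANhyb_rscf00002550.1.g00001.1 in the total counts of each library, in percent, by group. Points are libraries with their replicate number, and bars give the mean ± SD of 3 libraries. Inoculated peat libraries lie between 5.97% and 6.79%, mock peat libraries between 0.979% and 1.66%.

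The effect of the fungus on leaves grown in peat was tested between inoculated and mock peat libraries. In this comparison, 28 gene models were higher and 31 lower after inoculation (edgeR quasi-likelihood test). FANhyb_rscf00000752.1.g00004.1 rose from 1.75 ± 0.90 to 34.2 ± 6.2 CPM, a log2 fold change of 4.27 ± 0.81 (SE) with an adjusted p of 0.0337. FANhyb_icon19730437_s.1.g00001.1 rose from 0.69 ± 0.68 to 11.8 ± 2.7 CPM (log2 4.04 ± 0.63, adjusted p = 0.00937). FANhyb_rscf00000003.1.g00046.1 fell from 48.2 ± 28.1 to 2.45 ± 0.66 CPM (log2 -4.30 ± 0.66, adjusted p = 0.0112), and FANhyb_rscf00003859.1.g00001.1 fell from 430 ± 267 to 22.6 ± 2.6 CPM (log2 -4.25 ± 0.82, adjusted p = 0.0414). These calls, in the order given, were lost in 5, 3, 5 and 6 of 16 other settings. The median log2 fold change was 1.78 among the 28 and -1.99 among the 31. The count rested on single libraries: it was 303 without mock peat replicate 1, which held FANhyb_rscf00003859.1.g00001.1 at 122 CPM against 594 and 573 in its group, 0 without mock peat replicate 2, 30 without mock peat replicate 3, and 3, 4 and 9 without inoculated peat replicates 1, 2 and 3. DESeq2 called 284.

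Inoculation of plants grown in chitin raised 139 and lowered 242 gene models (edgeR quasi-likelihood test). FANhyb_rscf00000752.1.g00004.1, also raised in peat, went from 2.30 ± 1.98 to 41.3 ± 22.7 CPM (log2 4.22 ± 0.81, adjusted p = 0.0162). FANhyb_rscf00000141.1.g00001.1 rose from 0.39 ± 0.30 to 18.3 ± 20.2 CPM, with inoculated libraries from 0.988 to 40.5 CPM (log2 5.48 ± 1.21, adjusted p = 0.0266). FANhyb_rscf00001263.1.g00002.1 held 317 counts in mock and 0 in inoculated chitin libraries and was at least 117-fold lower after inoculation, against 3 counts over the group (adjusted p = 0.0177). FANhyb_rscf00002447.1.g00002.1 held 2493 counts in mock and 3 in inoculated chitin libraries, a ratio of 921 (95% interval 315 to 4471, adjusted p = 0.0131). Mock chitin replicate 1 carried most of both lowered gene models, with 28.8 CPM of FANhyb_rscf00001263.1.g00002.1 against 1.56 and 1.95 CPM, and 190 CPM of FANhyb_rscf00002447.1.g00002.1 against 3.85 and 79.9 CPM. Limma voom called neither of them (adjusted p = 0.127 and 0.300) nor FANhyb_rscf00000141.1.g00001.1 (adjusted p = 0.325). Without mock chitin replicate 1, edgeR called neither FANhyb_rscf00001263.1.g00002.1 (adjusted p = 0.0701) nor FANhyb_rscf00000141.1.g00001.1 (adjusted p = 0.161) nor FANhyb_rscf00000752.1.g00004.1 (adjusted p = 0.0703). The count was 66 without mock chitin replicate 1, 593 and 199 without mock chitin replicates 2 and 3, and 189, 84 and 831 without inoculated chitin replicates 1, 2 and 3. It was 0 when only these 6 libraries were fitted, 248 with limma voom and 976 with DESeq2.

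The inoculation calls of peat and chitin, which compare different libraries within a single fit, shared 21 higher and 19 lower gene models. Independent lists would share 0.260 and 0.502, but the filter and estimate of the spread were common to both lists and can raise the overlap. No gene model was called in opposite directions (0). Of the 28 gene models raised in peat, 27 were also positive in chitin, with a median log2 fold change of 1.38, and all 31 lowered in peat were negative in chitin (median -1.52). Across all 14946 gene models, which are not independent replicates, the 2 sets of log2 fold changes correlated with r = 0.382 and rho = 0.344.

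In biochar, no gene model passed the threshold for inoculation (edgeR quasi-likelihood test, 0 higher and 0 lower), 710 had an unadjusted p under 0.05, limma voom called 0 and DESeq2 19. Of the gene models called in peat, 26 of the 28 raised had a positive and 29 of the 31 lowered a negative log2 fold change in biochar, with medians of 0.79 and -0.9999. Of those called in chitin, 119 of the 139 raised were positive and 154 of the 242 lowered were negative in biochar. Their medians were 0.43 and -0.19 in biochar, 0.65 and -0.87 in peat, and 1.41 and -2.06 in chitin. The chitin libraries set these calls, which enlarges the medians in chitin, so they are no fair reference for those in biochar. FANhyb_rscf00000752.1.g00004.1 stood at 2.30 ± 2.09 CPM in mock and 18.6 ± 13.4 CPM in inoculated biochar leaves, and FANhyb_icon19730437_s.1.g00001.1 at 0.50 ± 0.26 and 5.04 ± 2.21 CPM. Over all gene models, inoculation effects in biochar correlated with those in peat (r = 0.284, rho = 0.246) and in chitin (r = 0.148, rho = 0.117). The 95% limma voom interval of the inoculation effect lay within 2-fold either way for 6320 gene models (42.3%).

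Averaged over the 3 substrates, inoculation raised 280 and lowered 469 gene models (edgeR quasi-likelihood test). FANhyb_rscf00000752.1.g00004.1 (log2 3.83 ± 0.46, adjusted p = 0.000259) and FANhyb_icon19730437_s.1.g00001.1 (log2 3.72 ± 0.37, adjusted p = 3.9e-05) had the largest rises among the gene models that passed the rule for naming, and each was higher in all 9 inoculated than in all 9 mock libraries. FANhyb_rscf00000030.1.g00022.1 fell by 3.94 on the log2 scale (SE 0.61, adjusted p = 0.00179), from 10.8 to 0.87 CPM in peat, 6.85 to 1.54 CPM in biochar and 13.3 to 0.21 CPM in chitin. FANhyb_rscf00002447.1.g00002.1 fell by 4.18 (SE 1.00, adjusted p = 0.0290), although its mean in biochar was 0.48 CPM in mock and 1.36 CPM in inoculated leaves. This call was lost in 10 of 27 other settings, among them limma voom (adjusted p = 0.266) and the edgeR fit without mock biochar replicate 3 (adjusted p = 0.166). Within the single substrates, 279 of the 280 raised gene models were positive in peat, 274 in biochar and 279 in chitin, with medians of 0.87, 0.54 and 1.01. Of the 469 lowered, all were negative in peat and in chitin and 428 in biochar, with medians of -1.09, -0.62 and -1.39. The same libraries set the calls, so these signs are not an independent test. The count was 1155 without mock peat replicate 1 and 427 to 497 without mock biochar replicate 3, mock chitin replicate 1, inoculated peat replicates 1 or 3, or inoculated biochar replicate 2. DESeq2 called 1237, and 342 had an absolute log2 fold change of at least 1.

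**Figure D3:**
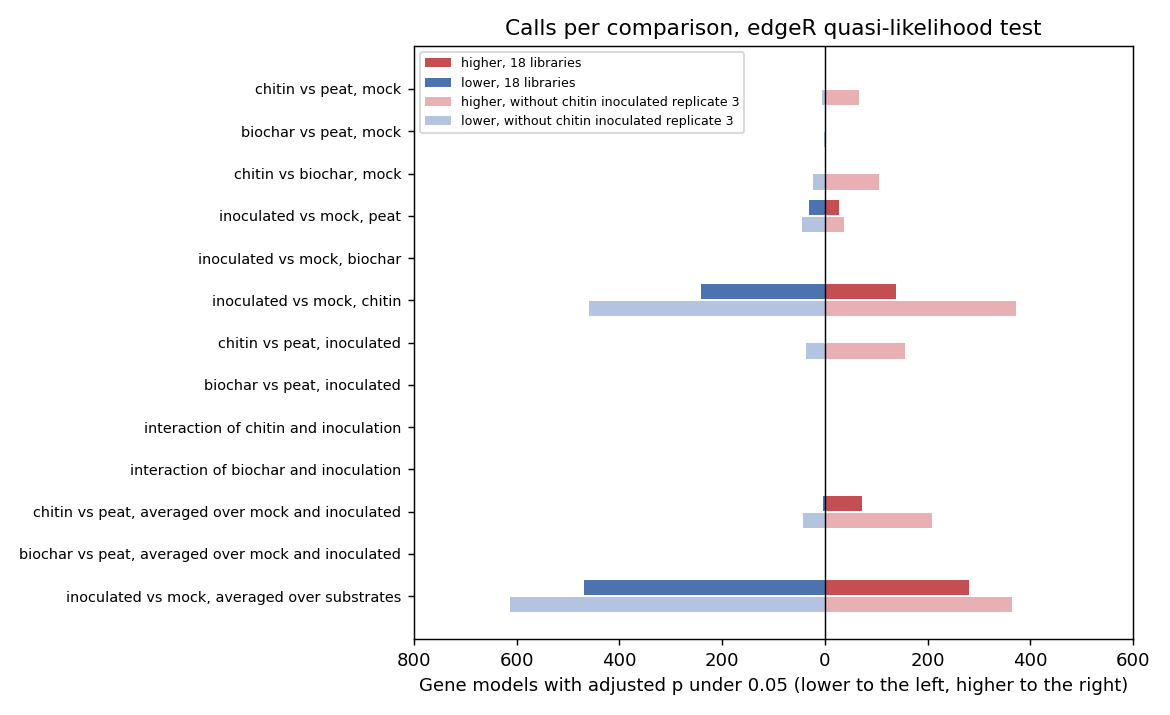
Number of gene models with an adjusted p under 0.05 in each of the 13 comparisons (edgeR quasi-likelihood test), lower to the left and higher to the right. Dark bars use 18 libraries, and pale bars leave out inoculated chitin replicate 3. Inoculation averaged over substrates gives 280 higher and 469 lower with 18 libraries.

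The effect of chitin without the fungus was tested between mock chitin and mock peat leaves. FANhyb_rscf00001561.1.g00001.1 was the gene model that passed, at 39.97 ± 6.87 CPM in chitin and 6.41 ± 1.91 CPM in peat (log2 2.64 ± 0.40, adjusted p = 0.0494, edgeR quasi-likelihood test). In inoculated leaves it stood at 36.6, 43.3 and 9.79 CPM in the chitin libraries and at 8.16 ± 1.71 CPM in peat. It was 1 of 1270 gene models with an unadjusted p under 0.05, of which 755 were higher in chitin. Without inoculated chitin replicate 3, which enters here through the shared filter and estimate of the spread, 66 gene models were higher and 5 lower, and a fit of only the 6 mock libraries compared called 24 higher and 1 lower. FANhyb_rscf00001561.1.g00001.1 lost its call without each of the 6 libraries compared and with limma voom (adjusted p = 0.169), and DESeq2 called 105.

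Chitin and biochar were compared directly in mock leaves. FANhyb_rscf00001142.1.g00002.1 was higher in chitin, at 149 ± 39 CPM against 10.7 ± 1.0 CPM in biochar and 21.6 ± 7.6 CPM in peat (log2 3.80 ± 0.48 against biochar, adjusted p = 0.00988, edgeR quasi-likelihood test). Its inoculated chitin libraries stood at 149, 133 and 24.3 CPM, replicate 3 being the lowest, and inoculated biochar at 17.9 ± 1.7 CPM. It was the sole call (1 higher, 0 lower) among 1579 gene models under an unadjusted p of 0.05. Without inoculated chitin replicate 3, 106 gene models were higher and 23 lower in chitin, without mock peat replicate 1 they were 8 and 2, and without mock chitin replicate 2 the count was 21. It was 0 without any 1 of the biochar libraries and with limma voom, 85 in a fit of the 6 libraries alone and 261 with DESeq2.

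In inoculated leaves, no gene model differed between chitin and peat at the threshold (edgeR quasi-likelihood test, 0 higher and 0 lower), 832 had an unadjusted p under 0.05, limma voom called 0 and DESeq2 88. A chitin score was taken over the 90 gene models that were higher in chitin among the 100 with the smallest p in a fit of the mock chitin and peat libraries alone, most of them not called. These gene models had a mean log2 CPM of 6.09 and 5.69 in inoculated chitin replicates 1 and 2. It was 2.92 in replicate 3 and 2.94 to 3.39 in inoculated peat. Means of this chitin score were 4.90 ± 1.73 in inoculated chitin and 3.22 ± 0.24 in inoculated peat, with a two-sided exact permutation p of 0.4 (smallest possible 0.1). Without inoculated chitin replicate 3, 156 gene models were higher and 36 lower in inoculated chitin than in inoculated peat. That library was left out because of its values, so these counts are not an independent test.

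**Figure D4:**
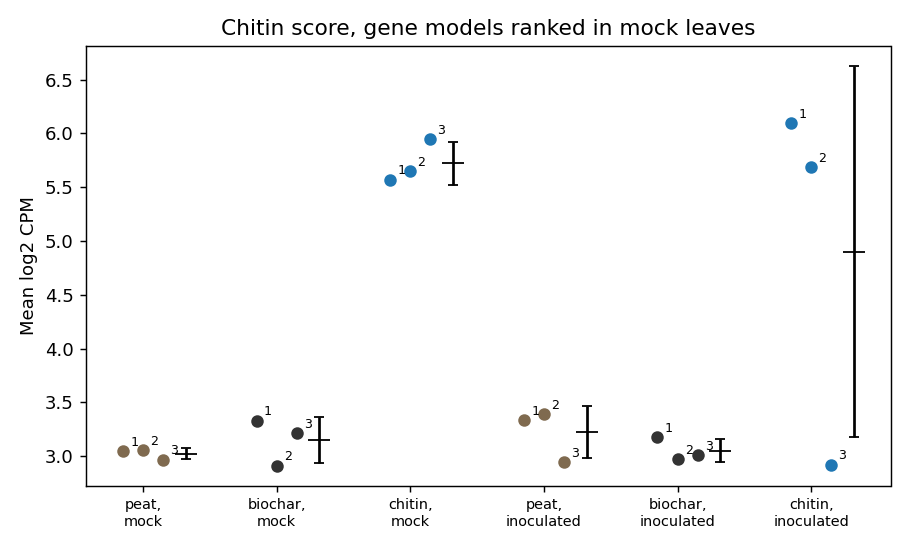
Mean log2 CPM of the 90 gene models that were higher in mock chitin among the 100 ranked by p against mock peat, per library and group. Points are libraries with their replicate number, and bars give the mean ± SD of 3 libraries. Inoculated chitin replicate 3 lies at 2.92, within the range of the peat and biochar libraries (2.91 to 3.39), and the other chitin libraries lie at 5.57 to 6.09. The separation of mock chitin from mock peat follows from the choice of gene models.

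Averaged over mock and inoculated leaves, chitin raised 73 and lowered 4 gene models against peat (edgeR quasi-likelihood test). FANhyb_rscf00002154.1.g00001.1 held 1603 counts in the chitin and 5 in the peat libraries, a ratio of 314 (95% interval 134 to 968, adjusted p = 0.0222). Of these 5 counts 4 lay in inoculated peat replicate 1, so that library set the ratio, and without it the fitted log2 fold change went from 9.20 to 9.99 and the call was lost (edgeR adjusted p = 0.0789). FANhyb_rscf00004635.1.g00001.1 held 249 counts against 1, a ratio of 244 (95% interval 43.4 to 9672, adjusted p = 0.0109). That single count lay in mock peat replicate 1, so without that library the ratio would be a bound only. Both were at 0.18 CPM in inoculated chitin replicate 3, where the other chitin libraries held at least 8.99 and 1.98 CPM. FANhyb_rscf00000003.1.g00040.1 fell by 1.00 on the log2 scale (SE 0.22, adjusted p = 0.0467) and FANhyb_rscf00007427.1.g00001.1 by 0.79 (SE 0.17, adjusted p = 0.0420). Their means in mock leaves were 256 ± 66 against 450 ± 208 CPM and 13.3 ± 0.9 against 27.8 ± 7.7 CPM. For FANhyb_rscf00000003.1.g00040.1 the mock groups overlapped, with mock peat replicate 1 at 245 CPM and mock chitin replicate 1 at 330 CPM. Limma voom called neither of these 2 lowered gene models (adjusted p = 0.105 and 0.102) nor FANhyb_rscf00002154.1.g00001.1 (adjusted p = 0.734) and FANhyb_rscf00004635.1.g00001.1 (adjusted p = 0.304), and the 4 calls were lost in 11, 12, 11 and 2 of 21 other settings. All 73 raised gene models were positive both in mock (median log2 2.37) and in inoculated leaves (median 2.19), over the libraries that set the calls. Leaving out inoculated chitin replicate 3 gave 209 higher and 42 lower, leaving out any other library of the 4 groups gave 14 to 88, limma voom gave 20 and DESeq2 213.

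Biochar changed no gene model at the threshold against peat, either in mock leaves (770 with an unadjusted p under 0.05), in inoculated leaves (642) or averaged over both (1025), each with 0 higher and 0 lower in edgeR's quasi-likelihood test. Limma voom called 0 in all 3 comparisons, and DESeq2 called 11, 4 and 9. Without inoculated chitin replicate 3, 1 gene model was lower in biochar in mock leaves. The 95% limma voom interval lay within 2-fold either way for 6305 gene models (42.2%) in mock leaves, 6536 (43.7%) in inoculated leaves and 9163 (61.3%) for the average. A fit of the inoculated biochar and peat libraries alone called 66 gene models, 44 higher and 22 lower in biochar. Leaving out inoculated biochar replicate 2 gave 7 calls in inoculated leaves and 4 for the average.

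Whether an amendment altered the response to the fungus was tested by interactions. Neither chitin (923 gene models with an unadjusted p under 0.05) nor biochar (486) gave a call, with 0 higher and 0 lower in edgeR's quasi-likelihood test, 0 with limma voom, and 15 and 2 with DESeq2. Without mock peat replicate 1, the chitin interaction had 1 higher and 1 lower. The 95% limma voom interval lay within 2-fold either way for 3290 gene models (22.0%) for chitin and 3396 (22.7%) for biochar, so larger differences in response were not excluded for the others. The counts of inoculation calls in peat, biochar and chitin do not by themselves show that the responses differed.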

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

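The scores per library and the tests of the 3 patterns weighed here were chosen after the results were seen, except the mixing test of mock peat replicate 1, the test of a swap with mock peat and the comparison of spread between substrates.

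The response to inoculation was compared between peat and biochar with a score, and its difference passed 0.05 before but not after adjustment. The score was the mean log2 CPM of the 139 gene models raised by inoculation in chitin minus that of the 242 lowered. Its gene models were chosen on the contrast of chitin libraries and compared on others. The fit behind that choice took its filter and estimate of the spread from all libraries, so choice and comparison were not fully separate. It rose by 1.78 in peat and by 0.76 in biochar, a difference of 1.02 (exact permutation test within disc treatments, two-sided p = 0.035, 0.07 after Benjamini-Hochberg adjustment over 2 such scores). The score from the 28 raised and 31 lowered in peat rose by 1.97 in biochar and 3.30 in chitin (difference -1.33, exact permutation p = 0.235). These tests exchange substrate labels within each disc treatment, so they assume no substrate effect in mock or in inoculated leaves. They are therefore not exact tests of a difference in response alone.

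Fewer calls for inoculation in biochar (0) than in peat (59) or chitin (381) were weighed against 2 technical explanations. Depth is argued against, since after all libraries were thinned to one total peat had 68 calls, 56 of them among its 59, chitin had 351, 327 of them among its 381, and biochar had 0. Over both disc treatments the spread between biochar replicates was not larger than in peat or chitin. The median SD within groups was 0.381 log2 CPM in biochar, 0.398 in peat and 0.478 in chitin. Among inoculated libraries it was 0.326 in biochar and 0.273 in peat. All groups shared the estimate of the spread, so the SD of a substrate does not by itself set its count. A fit of the chitin libraries alone gave 0 calls for inoculation, so spread as an explanation stays undecided. A smaller response of biochar-grown leaves stays open: the score difference of 1.02 fell to 0.72 (exact permutation p = 0.155) when the score was rebuilt without inoculated chitin replicate 3, and its p ran from 0.01 to 0.08 when single peat or biochar libraries were left out, at 0.05 or above without mock peat replicate 2 or 3, mock biochar replicate 2 or any inoculated peat replicate.

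Inoculated chitin replicate 3 had a low chitin score, over 90 gene models ranked in mock leaves and not each called. Its score of 2.92 lay among the 12 peat and biochar libraries (2.91 to 3.39), and its log2 CPM correlated with inoculated peat and biochar libraries at 0.947 to 0.968, against 0.903 and 0.931 with its own group. A swap with a biochar or inoculated peat library is argued against, because the highest score among these 9, which had no part in choosing the gene models, was 3.39, against 6.09 and 5.69 in inoculated chitin replicates 1 and 2. A swap with a mock peat library is argued against by a score of 84 gene models ranked against mock biochar instead, with at most 3.75 in mock peat against 6.15 and 5.85 in these 2 libraries, and low depth by a total of 11.2 M counts. A wrong substrate label, or a sample from outside the series, may explain the score of 2.92, and a plant that did not take up or respond to chitin may explain it as well: 80% of the 90 gene models lay within the range of the peat and biochar libraries, and both explanations predict this, so they cannot be told apart.

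Mock peat replicate 1 lay nearer to inoculated libraries than the other mock peat libraries did. On a score of 60 gene models raised and 90 lowered by inoculation in biochar and chitin, it stood at 0.18, mock peat replicates 2 and 3 at -0.82 and -1.14, and inoculated peat libraries at 2.00 to 2.24. A mislabelled inoculated peat library is argued against by this gap at 0.18. A mislabelled inoculated biochar or chitin library was not tested. Mixing of inoculated peat reads into a library like mock peat replicates 2 and 3 would give equal shares over raised and lowered gene models. These shares, of the way to the inoculated peat level, came from summed CPM, so abundant gene models weighed most. FANhyb_rscf00002550.1.g00001.1 was kept out of the raised gene models and gave 8.55% on its own. The share was 5.77% over the raised and 80.1% over the lowered gene models. The difference was 74.4 percentage points (95% bootstrap interval over gene models 19.3 to 100.1), which argues against that case alone. Gene models are not independent, and the interval holds no spread between libraries. Mixing with an inoculated biochar or chitin library was not tested. Low depth is argued against by its total of 8.01 M counts beside a median of 8.18 M in the 6 peat libraries, and no biological explanation was tested.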

How the results depend on the processing

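Counts below are gene models with an adjusted p under 0.05, by edgeR unless another tool is named, and are given where they moved by over 1.5 times or to or from 0. With the planned settings, 342 of the 749 called for averaged inoculation had an absolute log2 fold change of at least 1. At 5 CPM in 3 libraries and with median-of-ratios size factors, chitin in mock leaves had 0 calls.

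With no filter on low counts, calls were 466 for chitin, 284 for biochar and 690 for chitin against biochar in mock leaves, 448 for chitin and 260 for biochar in inoculated leaves, and 481 and 456 for their averages. Inoculation then had 642 in peat, 159 in biochar, 1478 in chitin and 1642 averaged, and the interactions had 388 for chitin and 104 for biochar. For biochar in mock leaves, other splits of the libraries gave a median of 244 without the filter. Other splits were not run without the filter for the other comparisons, and none of these counts is used as a result.

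DESeq2, whose share of false calls in simulations was 10.5% to 20.5%, called 105 for chitin, 11 for biochar and 261 for chitin against biochar in mock leaves, 88 for chitin and 4 for biochar in inoculated leaves, and 213 and 9 for their averages. For inoculation it called 284 in peat, 19 in biochar, 976 in chitin and 1237 averaged, and 15 and 2 for the chitin and biochar interactions. Limma voom called 0 for chitin and 0 for chitin against biochar in mock leaves, 248 for inoculation in chitin and 20 for averaged chitin.

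With the replicate block, calls were 0 for chitin and 6 for chitin against biochar in mock leaves and 47 for averaged chitin. The replicate numbers did not mark pairs: 4 of 18 libraries correlated best with a library of their own number. Fits of only the 2 groups compared gave 25 for chitin, 1 for biochar and 85 for chitin against biochar in mock leaves, 0 for inoculation in chitin and 66 for biochar in inoculated leaves.

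Alternatives chosen after the data were seen follow. Without mock peat replicate 1 and inoculated chitin replicate 3 together, calls were 111 for chitin and 201 for chitin against biochar in mock leaves, 261 for chitin in inoculated leaves, 310 for averaged chitin and 11 for the chitin interaction. Inoculation then had 456 in peat, 1114 in chitin and 1657 averaged. Limma voom with sample quality weights gave 26 for chitin and 172 for chitin against biochar in mock leaves, 85 for chitin in inoculated leaves, 194 for averaged chitin, and 272 in peat, 11 in biochar and 1314 averaged for inoculation. After thinning to the lowest total, chitin and biochar in mock leaves had 0 and 1.

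Leaving out single libraries of the groups compared gave ranges of 0 to 0 for chitin, 0 to 0 for biochar and 0 to 21 for chitin against biochar in mock leaves. In inoculated leaves they were 0 to 192 for chitin (192 without inoculated chitin replicate 3) and 0 to 7 for biochar, and for the averages 14 to 251 for chitin and 0 to 4 for biochar. Inoculation had 0 to 303 in peat, 0 to 0 in biochar, 66 to 831 in chitin and 427 to 1155 averaged. The interactions had 0 to 2 for chitin and 0 to 1 for biochar. The difference between score rises in peat and biochar ran from 0.87 to 1.32, and was 0.72 with the score rebuilt without inoculated chitin replicate 3.

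Of the values of single gene models and of the settings they were tried in, 354 stayed the same, 100 became weaker, 9 stronger and 3 reversed, and 1 with no adjusted p in DESeq2 was left out. Those that stayed the same kept their sign and their call or, if uncalled in the main setting, stayed uncalled. They are therefore not all calls that held. The reversed values were the uncalled chitin interaction of FANhyb_rscf00002550.1.g00001.1, at -0.19 without mock chitin replicate 1, -0.22 without inoculated chitin replicate 2 and -0.18 with limma voom and sample quality weights. Over single libraries left out it ran from -0.22 to 0.86. In mock leaves, the call of FANhyb_rscf00001561.1.g00001.1 for chitin was lost in 11 of 16 settings and that of FANhyb_rscf00001142.1.g00002.1 against biochar in 4 of 16. For averaged chitin, FANhyb_rscf00007427.1.g00001.1 lost its call in 12 of 21 settings, FANhyb_rscf00000003.1.g00040.1 and FANhyb_rscf00002154.1.g00001.1 in 11 of 21 each, and FANhyb_rscf00004635.1.g00001.1 in 2 of 21. For averaged inoculation, FANhyb_rscf00002447.1.g00002.1 lost it in 10 of 27, FANhyb_rscf00000030.1.g00022.1 in 1 of 27, and the 2 named raised gene models in 0 of 27. For inoculation in peat, FANhyb_rscf00003859.1.g00001.1 lost it in 6 of 16, FANhyb_rscf00000752.1.g00004.1 and FANhyb_rscf00000003.1.g00046.1 in 5 of 16 each, and FANhyb_icon19730437_s.1.g00001.1 in 3 of 16. For inoculation in chitin, FANhyb_rscf00001263.1.g00002.1 lost it in 6 of 14, FANhyb_rscf00000141.1.g00001.1 in 5 of 15, FANhyb_rscf00002447.1.g00002.1 in 4 of 16, and FANhyb_rscf00000752.1.g00004.1 and FANhyb_rscf00002550.1.g00001.1 in 2 of 16 each. The latter gained a call in peat in 8 of 16 and in biochar in 1 of 16. Other settings for the gene lists fixed beforehand were not run, since no identifier could be assigned to a list.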

Other observations

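The test of calls on gene models with few reads and the look at which libraries the highest splits moved were chosen after the results were seen. The tests of shared direction, of neighbouring gene models and of other splits were set out before their results were seen, except the splits for inoculation in peat.

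Inoculation calls lay beside one another more often than chance. Among 5254 pairs of tested gene models with consecutive numbers on a scaffold, 22 pairs were called in the same direction for inoculation averaged over substrates, 10 higher and 12 lower. Draws of as many gene models matched on expression gave a mean of 7.17 and at most 19 (one-sided permutation p = 0.0001, the smallest that 10000 draws can give), and 4 pairs were called in opposite directions. The 22 pairs are consistent with neighbouring copies that respond together, with a gene split over 2 gene models and with reads shared between neighbours, which were not tested for want of sequences. For chitin averaged over disc treatments, 1 pair was found against a mean of 0.0936 (permutation p = 0.09), not more than the draws give.

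The hypothesis that an amendment moves leaf transcripts in the direction of inoculation had no backing here. Across gene models, the chitin effect in mock leaves correlated with the inoculation effect in biochar at r = 0.0164, and 91 of 100 relabellings of the 12 libraries, the real one included, gave a correlation at least as large in size (largest other 0.353). The biochar effect in mock leaves correlated with the inoculation effect in chitin at r = 0.0446, matched by 81 of 100 relabellings (largest other 0.337). Correlations of this size cannot be read as either presence or absence of a shared direction.

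Other splits of the same libraries were fitted in the same way. For inoculation averaged over substrates, 1 of 100 splits, the real one, gave as many as 749 calls (highest other 15). For chitin averaged over disc treatments 2 of 100 gave as many as 77 (highest other 155). The splits were drawn from 4000 possible for inoculation and 200 for chitin. At these shares a chance arrangement of the libraries is unlikely but not excluded. The split with 155 calls kept both mock groups whole and exchanged inoculated chitin replicate 3 with inoculated peat replicate 2, so it holds most of the substrate difference itself. For the interactions and for biochar averaged over disc treatments all 100 of 100 splits gave at least the 0 calls observed, with highest others of 89 for the chitin interaction, 0 for the biochar interaction and 0 for biochar. The split with 89 calls kept the chitin groups whole and mixed mock with inoculated peat libraries, so it holds the inoculation effect in chitin. Comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. The real count was reached in 1 of 10 for inoculation in peat (59, highest other 0), for inoculation in chitin (381, highest other 0) and for chitin against biochar (1, highest other 0). It was reached in 4 of 10 for chitin against peat in mock leaves (1, highest other 5). It was reached in 10 of 10 for the comparisons with 0 calls, where the highest other was 4 for chitin against peat in inoculated leaves and 0 for inoculation in biochar and for biochar against peat in mock and in inoculated leaves.

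Without a filter on low counts, edgeR called 284 gene models for biochar against peat in mock leaves. Few of them, 1.76%, lay on gene models that the filter removes, which argues against an excess among gene models with few reads. The 9 other splits of the same 6 libraries gave a median of 244 calls and up to 371 without the filter, so calls of that fit carry no evidence of a biochar effect. The median prior degrees of freedom were infinite in that fit and 6.07 with the filter.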
